A study of Mus musculus with 12 samples.

How the data were processed

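The study profiled total RNA from the cerebral cortex of 12 mouse embryos at embryonic day 15.5, 6 Emx1-Cre Arid1a conditional mutants and 6 controls, all labelled as batch 1. Per the labels' protocols, cortices were dissected fresh, RNA was extracted with Trizol and treated with DNase, 600 ng went into each library, and ribosomal RNA was depleted. Libraries were made by ClickSeq, in which random-primed reverse transcription is stopped by azido-nucleotides and the adaptor, with a random molecular tag, is joined by click chemistry in place of fragmentation and ligation. Per the submitters' processing notes, bcl2fastq 2.17, UMI-tools 0.5.3, cutadapt 1.13, STAR 2.5.2a, HTSeq 0.6.1p1 and edgeR 3.20.9 were used with the mouse build mm10. The order of these steps, the annotation release, the counting mode and the feature type are not given in the sources used here. The deposited files hold raw counts, whole numbers per Ensembl gene with 1 library per file, to which the authors applied no normalization. How far molecular tags were collapsed could not be read from the files, so counting error alone may understate the error of a single library.

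Each file listed 51912 genes and 5 closing entries that name no gene, in the form HTSeq writes. The closing entries took 20.7 to 31.6% of a file's total, mostly alignments that were not unique (13.6 to 23.0%) and alignments on no feature (4.89 to 6.83%). They were left out, and so was the not-aligned entry. None of 5 library measures passed a comparison of mutants and controls (two-sided exact permutation test, n = 6 each). The smallest p was that of the share not unique, 18.5% ± 2.93 in mutants and 15.9% ± 2.19 in controls (SD, exact permutation p = 0.102, adjusted p = 0.417). Gene counts per library ran from 643197 to 3525121. Symbols, coordinates and gene types were taken from GENCODE M21 (GRCm38, the assembly of mm10): 47648 identifiers matched with their version and 3985 without it, 279 had no match, and 27629 genes had a count of 0 in every library. No 2 libraries were copies of one another (chi-square per degree of freedom from 1.97 to 16.6 over all pairs). Xist and Y-linked counts were checked against the labelled sex. The first 3 principal components of log2 CPM held 20.9, 16.2 and 14.1% of the variance. Residual profiles, with genotype means removed, correlated at a median of 0.0107 over the 30 pairs of libraries from the same litter and -0.148 over the 36 pairs from different litters. Removing the means itself lowers the correlation between libraries of the same genotype. Over pairs of unlike genotype the medians were 0.0270 (16 pairs, same litter) and -0.0039 (20 pairs, different litters).

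Genes were kept by filterByExpr with genotype as the group and its minimum count of 10, which left 10678. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with terms for litter, sex and genotype and 8 residual degrees of freedom, by estimateDisp, glmQLFit with robust = TRUE and glmQLFTest. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of the F statistic. Per-library levels are CPM scaled by the TMM library sizes, with mean and SD over the 6 libraries of a group. Within-litter log2 fold changes come from fits to that litter alone, with a sex term and no filter. In litter 1, with no male mutant, that leaves control 1 as the 1 control that informs genotype. The interaction of litter and genotype was tested in a model with that further term, and the sex comparison is the sex term of the same model as genotype. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as other tests. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

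The comparisons, the model, the gene lists, the rule for named genes and all alternatives except 4 were fixed before the data were examined. The rule names Arid1a, Emx1, the subplate markers Nr4a2, Ccn2, Cplx3, Lpar1, Tmem163 and Moxd1 and the layer markers Tbr1, Tle4 and Bcl11b whatever their result, and 1 further gene that is not used here. It adds the 10 genes higher and the 10 genes lower with the largest fold change among those called, with a mean of at least 1 CPM, the same sign in both litters and a proper symbol, and up to 4 called members of each list. The 30 lists cover subplate, layer 6, layer 5 and upper-layer neurons, radial glia, intermediate progenitors, cell cycle, p53 targets, integrated stress response, axon guidance, extracellular matrix, synapse, BAF and PBAF subunits, Wnt targets, immediate early genes, hypoxia and glycolysis, mitochondrial transcripts, interneurons, ganglionic eminence and striatum, Cajal-Retzius cells, cortical hem and hippocampus, choroid plexus, thalamus, oligodendrocyte precursors, microglia, endothelial cells, pericytes, meninges, red blood cells and Hox clusters. They hold markers of cell types that a dissection could carry along. Lists with at least 3 measured members were tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, one way without comparing them with other genes. Called genes in each list were also tested with a two-sided Fisher's exact test against all genes tested. Where members are given as adjusted over the list alone, their edgeR p values were Benjamini-Hochberg adjusted within that list. That adjustment is weaker than the one over all genes and makes no correction across lists. A list's score in a library is the mean log2 CPM of its members minus their mean over the 12 libraries.

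The model was tested on simulated data with the depths, litters and sexes of these libraries. Of genes changed 1.5-fold, edgeR called 19 of 55 (34.5%), of genes changed 2-fold 57 of 72 (79.2%), and of genes changed 3-fold 63 of 71 (88.7%), with 9 of 10310 unchanged genes called. DESeq2 called 57 of 72 genes at 2-fold with 12 unchanged genes, and limma-voom 56 of 72 with 10. With no change simulated, 0 of 10490 genes were called. Changes under 1.5-fold were thus mostly below what these libraries can show. With 1 list shifted, 1 of 26 lists was called. Genes were drawn independently of each other, while the real lists had estimated correlations of up to 0.76. The simulation therefore does not show how often lists of correlated genes are called without a change.

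Alternatives fixed beforehand left out the litter term, the sex term or both. Others used DESeq2 size factors or upper-quartile scaling, the DESeq2 test, limma-voom, no filter, a filter of at least 1 CPM in at least 6 libraries, robust = FALSE, or an adjusted p under 0.01. Single litters, females alone, the genes outside X, Y and mitochondrial DNA, and the data without each library in turn were also fitted. The filter at 1 CPM had been meant as the stricter one but kept 13792 genes, more than filterByExpr did. The list tests for the interaction and between litters were added after seeing the data. Another 4 alternatives were chosen then too: counts drawn down to the depth of the shallowest library, the 2 shallowest libraries (mutants 1 and 4) left out, the trend of counts on gene span removed, and the striatal marker score as a covariate. Other splits of the 12 libraries into groups of the same sizes were drawn at random, 100 per comparison with the real one included.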

Results

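RNA was measured in 12 libraries of micro-dissected mouse cerebral cortex at embryonic day 15.5, 1 library per embryo. In 6 of them Arid1a, a DNA-binding subunit of the BAF chromatin remodelling complex, carried a conditional mutation driven by Emx1-Cre, a recombinase active in the progenitors of the dorsal telencephalon and their descendants. The other 6 were controls. Litter 1 gave 2 mutants and 4 controls, and litter 2 gave 4 mutants and 2 controls. The mutants were 5 females and 1 male, and the controls were 2 females and 4 males, so genotype overlapped in part with both litter and sex. Counts on genes ran from 643197 in mutant 1 to 3525121 in mutant 3, with 15193 to 17868 genes detected per library. Mutant 1, mutant 4 (794716 counts), mutant 2 (924066 counts) and mutant 6 (1070000 counts) were the 4 shallowest libraries, and the controls held 1476478 to 2815042 counts. The mean depth was 1548990 ± 1143250 counts in mutants and 2241020 ± 535181 in controls (SD, n = 6 each, two-sided exact permutation p = 0.206). Each adjusted p below comes from a fit across all genes with terms for litter, sex and genotype, and each log2 fold change is mutant minus control with its standard error (SE). Because of the litter and sex terms it can differ from the ratio of the mean normalised counts (CPM, counts scaled to a common library size).

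Mutant against control asks which genes depend on Arid1a in the developing cortex, in a study of subplate neurons and cortical connections. Arid1a itself (ENSMUSG00000007880.16, mm10 chromosome 4, 133679008 to 133756769, minus strand) stood at 447 ± 51.0 CPM in mutants and 510 ± 42.3 CPM in controls (SD, n = 6 each). Mutants 1 to 6 had 400, 420, 465, 396, 479 and 525 CPM of Arid1a, and controls 1 to 6 had 464, 474, 492, 515, 541 and 575 CPM. The log2 fold change of Arid1a was -0.30 (SE 0.0958, adjusted p = 0.277), so the lower level did not pass the test, and 5 of 6 mutants lay below the control mean. Within litter 2 the Arid1a value was -0.32, and within litter 1 it was -0.24. Litter 1 held no male mutant and 1 female control, so with the sex term each value for litter 1 alone sets mutants 1 and 2 against control 1, a lone sample assumed to vary like the other libraries, and is weak evidence within that litter. A gene total counts all exons together, so the loss of a floxed exon is not visible in it, and cells outside the Emx1 lineage keep the gene. Emx1, the gene that supplies the Cre promoter, had a log2 fold change of -0.13 (SE 0.348, adjusted p = 0.979), with 54.2 CPM in mutants and 49.2 CPM in controls.

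Of 10678 genes tested, 17 were lower and 6 were higher in mutant cortex. The largest fall was in Lmo7, which encodes a LIM and PDZ domain protein (ENSMUSG00000033060.15, chromosome 14, 101729957 to 101934710): 7.52 ± 2.91 CPM in mutants against 71.8 ± 44.1 CPM in controls (SD, n = 6 each), a log2 fold change of -2.66 (SE 0.357, adjusted p = 0.00961). Within litter 2 Lmo7 had -2.09, and in litter 1, against control 1 alone, -3.50. Rgs6, a regulator of G protein signalling (chromosome 12, 82588292 to 83162056), fell from 591 ± 131 to 216 ± 46.5 CPM, with a log2 fold change of -1.48 (SE 0.193, adjusted p = 0.00961). Lrrtm4, a leucine-rich repeat protein of synapses, fell from 671 ± 172 to 279 ± 48.4 CPM (log2 fold change -0.97, SE 0.146, adjusted p = 0.00961). Lrrtm4 had -0.67 within litter 2 and -1.57 in litter 1, against control 1 alone. In Lmo7, Rgs6 and Lrrtm4 all 6 mutants lay below all 6 controls.

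Sulf1, an extracellular enzyme that removes sulfate from heparan sulfate (ENSMUSG00000016918.15, chromosome 1, 12692277 to 12861192), fell to 7.24 ± 3.39 CPM from 22.97 ± 9.76 CPM in controls (log2 fold change -1.96, SE 0.321, adjusted p = 0.0108). Hs3st5, a heparan sulfate sulfotransferase, had a log2 fold change of -1.09 (SE 0.175, adjusted p = 0.0212), with 86.8 CPM in mutants and 207 CPM in controls. Without control 6 the value of Hs3st5 was -0.71 (adjusted p = 0.213), and its call was also lost without mutant 1, 2, 4 or 6 (0.0503 to 0.105). With the span trend removed the log2 fold change of Hs3st5 stayed at -1.08 and the SE grew to 0.201 (adjusted p = 0.0683), so that call ended on precision. Ust, a sulfotransferase of dermatan and chondroitin sulfate, moved by -0.94 (SE 0.151, adjusted p = 0.0108), from 137 to 69.8 CPM. Bcan, the proteoglycan brevican (ENSMUSG00000004892.13, chromosome 3, 87987531 to 88000230), fell to 5.57 ± 3.30 CPM from 21.7 ± 10.3 CPM (log2 fold change -1.79, SE 0.348, adjusted p = 0.0391). The call of Bcan was lost without control 1 (adjusted p = 0.277), without control 5 or 6 or any of mutants 1 to 5 (0.0579 to 0.122), and with limma-voom (0.0845). Sulf1, Hs3st5 and Ust were picked out together after their values were seen, and 19 other measured enzymes of glycosaminoglycan sulfation had a mean change of -0.12 (95% interval -0.31 to 0.08). Those 19 did not include Hs3st4, a heparan sulfate sulfotransferase measured in the layer 6 list (log2 fold change -1.04, SE 0.266). The fixed list for the extracellular matrix of the cortical wall held 26 measured genes, of which 1 (Bcan) was lower and 25 did not pass. Adjusted over the list alone, Bcan and Spock1, another proteoglycan (log2 fold change -1.18, SE 0.216), were lower. The list as a whole missed the threshold (camera adjusted p = 0.109, and adjusted p = 0.241 with an estimated correlation), and it passed without both covariates (0.0158), without the sex term (0.0417) and without control 6 (0.0475).

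The remaining named genes that fell were Fam196a (log2 fold change -1.35, SE 0.236, adjusted p = 0.0176), Efs, a docking protein for Src-family kinases (-1.18, SE 0.205, adjusted p = 0.0173), and Cdh20, a cadherin (-1.01, SE 0.203, adjusted p = 0.0466). Fam196a stood at 9.48 CPM in mutants and 26.5 CPM in controls, and Cdh20 at 18.5 and 41.2 CPM. Efs stood at 15.3 and 28.1 CPM, and mutant 6, at 23.2 CPM of Efs, lay apart from the 5 other mutants. The 6 lower genes outside the naming rule had log2 fold changes from -0.87 to -0.62.

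Among the 6 higher genes, Magel2, an imprinted gene of the Prader-Willi region (ENSMUSG00000056972.6, chromosome 7, 62377010 to 62381640), rose the most, to 11.9 ± 4.81 CPM from 2.59 ± 1.40 CPM (SD, n = 6 each, log2 fold change 1.85, SE 0.371, adjusted p = 0.0466). Sertm1 (chromosome 3, 54897068 to 54915887) rose to 25.04 ± 4.54 CPM from 8.37 ± 1.37 CPM (log2 fold change 1.53, SE 0.241, adjusted p = 0.00961). The call of Magel2 was lost without mutant 4 (adjusted p = 0.292), without control 1, 5 or 6 or mutant 1, 2, 5 or 6 (0.0707 to 0.133), in females (0.248) and with limma-voom (0.0845). In Magel2 and Sertm1 all 6 mutants lay above all 6 controls. Pdgfc, a ligand of the platelet-derived growth factor family, had a log2 fold change of 0.79 (SE 0.147, adjusted p = 0.0253), from 60.1 to 115 CPM. The call of Pdgfc was lost without control 1, 5 or 6 or any of mutants 1 to 4 (adjusted p = 0.0519 to 0.168), without the litter term (0.182), without both covariates (0.0593) and in females (0.0588). Caly, a vesicle protein of neurons, had 1.31 (SE 0.245, adjusted p = 0.0253), with 19.2 ± 6.85 CPM in mutants and 12.0 ± 4.39 CPM in controls and 2 of 6 mutants above all controls. The value of Caly rested on the sex term, at 0.75 (adjusted p = 0.365) without it and 0.58 (0.426) without both covariates, and its call was lost without control 6 or any of mutants 1 to 4 (0.0535 to 0.198). Synpo2, an actin-binding protein, rose by 1.21 (SE 0.244, adjusted p = 0.0473), at equal depth had 1.86 (0.0592), and lost its call without control 1 or 6 or any 1 mutant (0.0662 to 0.247). Ttc7 rose by 1.06 (SE 0.212, adjusted p = 0.0466), and it also differed between the litters, with a log2 fold change of 1.94 for litter 2 against litter 1 (adjusted p = 8.76e-05). Without the litter term Ttc7 had 1.66 (adjusted p = 0.460).

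**Figure D1:**
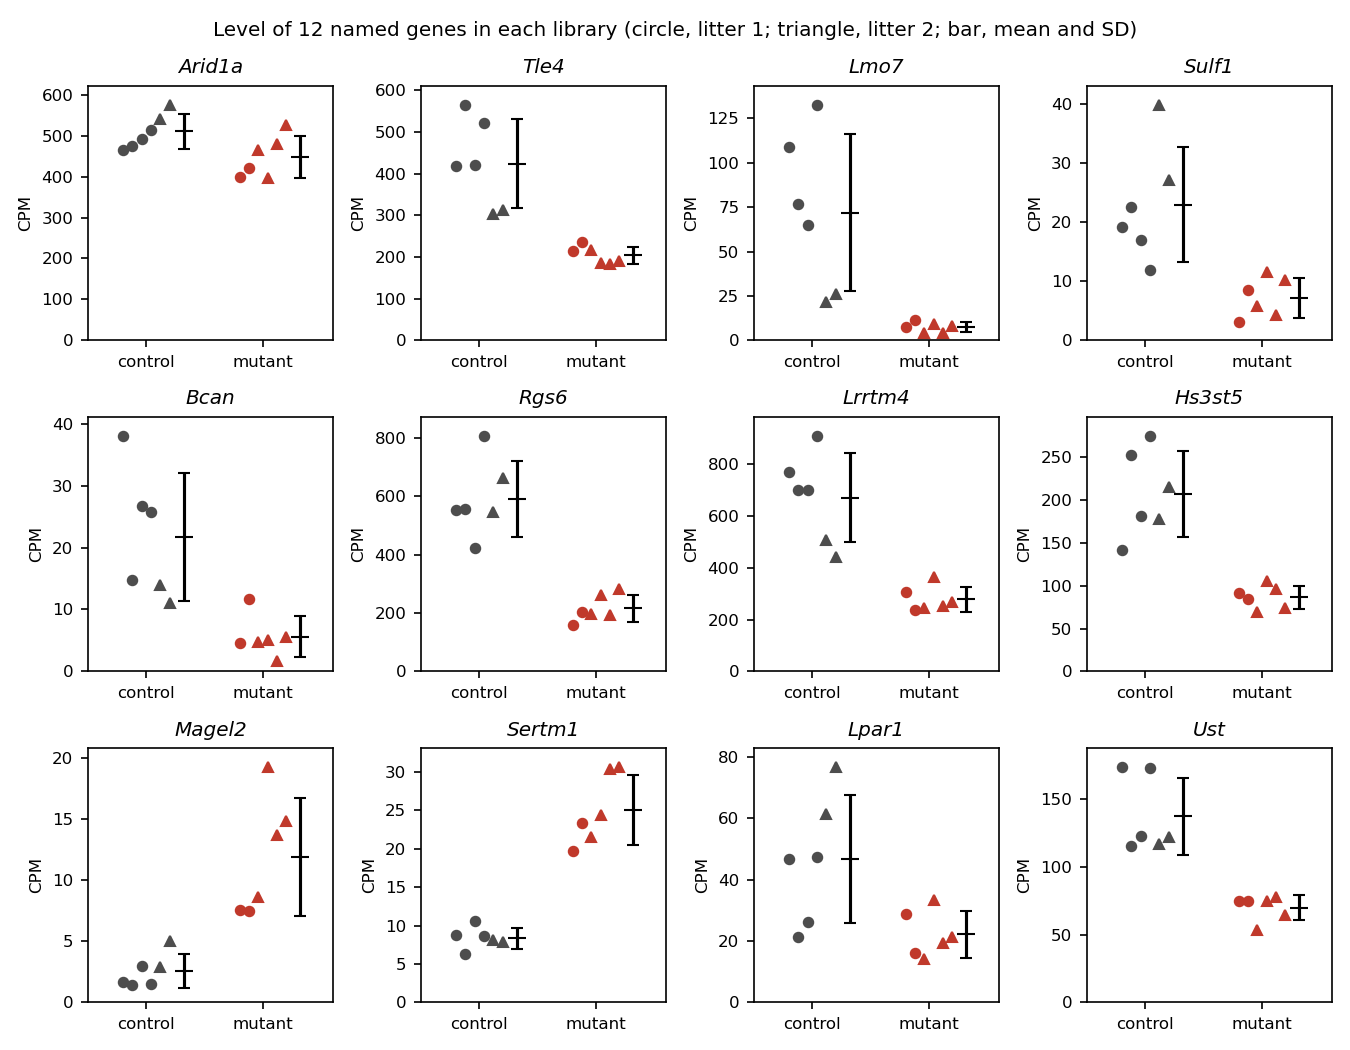
Level of 12 named genes in CPM (vertical axis) in each control (grey) and mutant (red) library, with circles for litter 1, triangles for litter 2, and the mean and SD of each group beside the points. All 6 mutants lay below all 6 controls for Tle4, Lmo7, Sulf1, Rgs6, Lrrtm4, Hs3st5 and Ust and above them for Magel2 and Sertm1, while the groups overlapped for Arid1a, Bcan and Lpar1.

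The counts come from the edgeR quasi-likelihood test at an adjusted p under 0.05. At an unadjusted p under 0.05, 541 genes were lower and 396 higher, against 533.9 expected by chance in all. All 6 mutants lay outside the control range in 16 of the 23 genes and in 135 of all genes tested, where chance would give 0.216% of genes if the 12 libraries were exchangeable, which the overlap of genotype with litter and sex does not grant. All 23 genes had the same sign in both litters, where litter 1 rests on control 1. The number of genes past the threshold was not stable. It was 0 without mutants 1 and 4, the shallowest libraries (700 genes at an unadjusted p under 0.05, limma-voom 0, DESeq2 42), although the 23 genes kept their signs there with a median ratio of 1.02 to the values above. Since the 23 genes were chosen in the same libraries, a shared sign in part of them adds little. Leaving out mutants 1 and 4 also removed the 1 male mutant and 1 of the 2 mutants of litter 1. Shallow depth as the cause of the lost calls therefore cannot be told apart from fewer samples and a fuller overlap of genotype with sex. Lower and higher genes numbered 9 and 1 without mutant 1, 5 and 1 without mutant 2, 11 and 3 without mutant 3, 10 and 2 without mutant 4, 16 and 3 without mutant 5, 11 and 6 without control 1, 37 and 7 without control 2, 45 and 10 without control 4, and 9 and 0 without control 6. Over the alternatives Sertm1 and Lrrtm4 kept their calls in 28 of 31, Tle4 and Rgs6 in 27, Lmo7 and Ust in 24, Hs3st5 in 22, Efs in 20, Pdgfc in 18, Synpo2 in 15, Cdh20 in 14 and Ttc7 in 11 of 31. Of 30, Sulf1 kept its call in 25, Fam196a in 20, Caly in 17, Magel2 in 16 and Bcan in 14. Without control 6 only 3 of the 23 genes passed, and without mutant 2 only 6, while all 23 passed without control 2 or control 4. In litter 2 alone 11 of the 23 passed, and in females 13. Leaving the sex term out gave 63 lower and 14 higher genes, and the DESeq2 test gave 77 and 18.

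**Figure D2:**
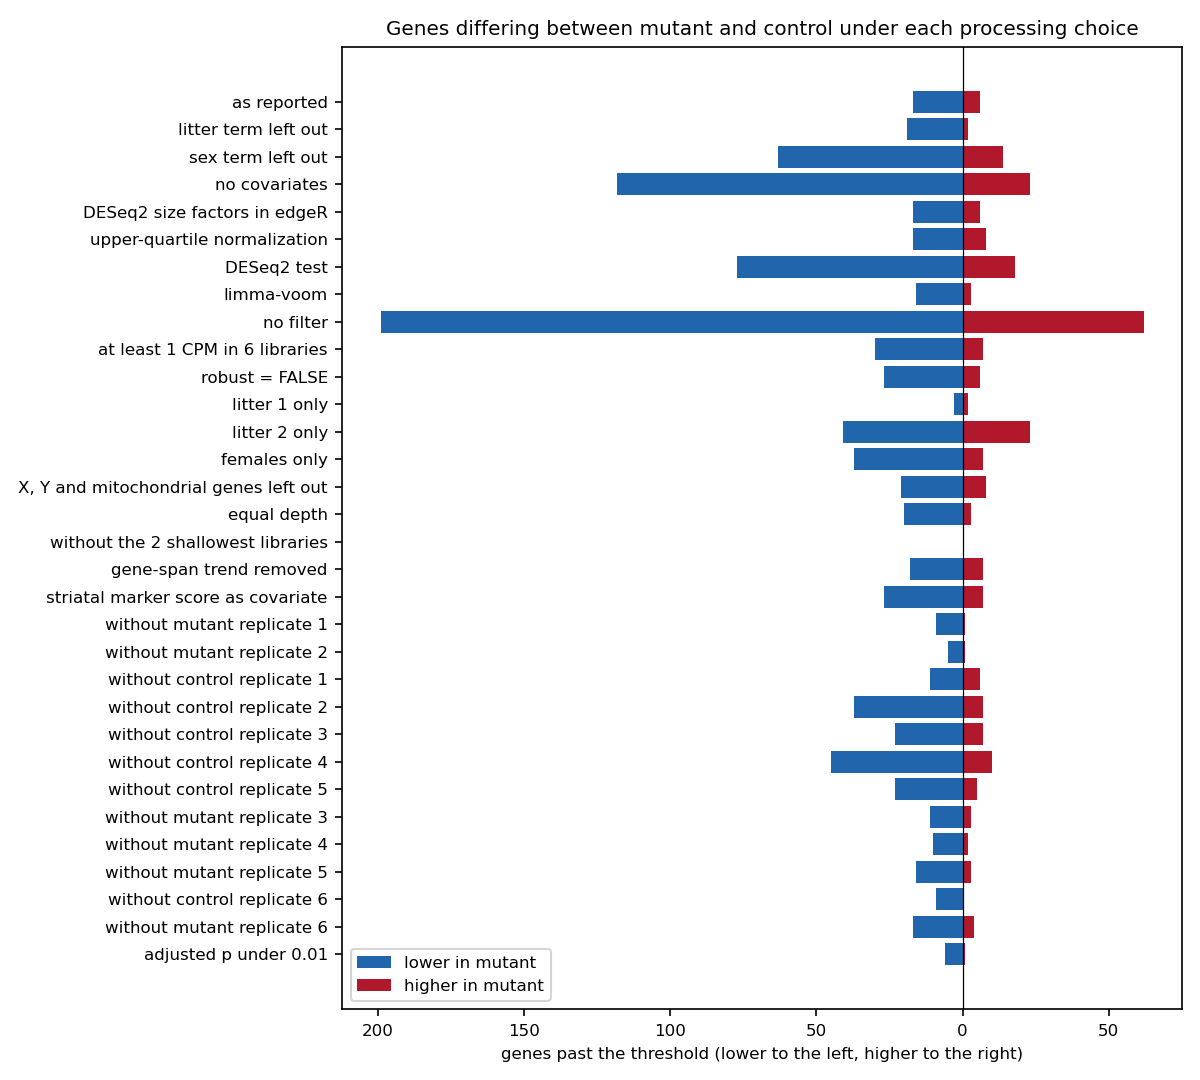
Number of genes past the threshold (horizontal axis, lower in mutant to the left of 0 and higher to the right) under each processing choice (vertical axis). The count as reported was 17 lower and 6 higher, lower genes outnumbered higher ones wherever any gene passed, and no bar stands where the 2 shallowest libraries were left out.

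Markers of layer 6 corticothalamic neurons fell as a list in mutant cortex by camera at a preset correlation (adjusted p = 0.00258), and the call was lost at adjusted p = 0.158 with an estimated correlation. Of its 12 measured members 1 fell, Tle4, and 11 did not pass, while 10 of the 12 had a negative log2 fold change. Tle4, a Groucho-family corepressor (ENSMUSG00000024642.16, chromosome 19, 14448150 to 14598051), stood at 204 ± 20.9 CPM in mutants against 424 ± 107 CPM in controls (SD, n = 6 each). Its log2 fold change was -0.81 (SE 0.121, adjusted p = 0.00961), with -0.68 within litter 2 and -0.96 in litter 1, against control 1 alone. Adjusted over the list alone, 4 members were lower, Tle4, Hs3st4 (-1.04, SE 0.266), Sla (-0.73, SE 0.1998) and Nfib (-0.45, SE 0.145), and 1 was higher, Lmo3 (0.93, SE 0.219). The fry adjusted p of the list was 0.0194. The camera value was 0.213 in litter 1 alone (1 control informative), 0.00102 in litter 2 alone and 0.110 without control 6, and it passed in 26 of 29 alternatives (7.82e-05 to 0.213). Tbr1, a transcription factor that specifies layer 6, did not pass, at -0.17 (SE 0.110, adjusted p = 0.737).

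Subplate neuron markers, the group that the study's title concerns, had no member past the threshold over all genes. All 15 measured members did not pass, 10 of them with a negative value. Adjusted over the list alone, 3 were lower: Lpar1, a lysophosphatidic acid receptor (log2 fold change -1.53, SE 0.338, adjusted p over all genes = 0.115), Zfpm2, a GATA cofactor (-1.16, SE 0.248, 294 ± 44.1 against 651 ± 207 CPM), and Serpini1, the protease inhibitor neuroserpin (-0.35, SE 0.119). Lpar1 stood at 22.2 ± 7.52 CPM in mutants and 46.7 ± 20.9 CPM in controls, and it passed in 5 of 31 alternatives (highest adjusted p = 0.687). These were females alone (adjusted p = 0.00622), litter 2 alone (0.0188), the DESeq2 test (0.0264), robust = FALSE (0.0495) and no filter (1.45e-10). With no filter 261 genes passed in all, so that last value is not on the scale of the others. Tmem163 had -0.61 (SE 0.299, adjusted p = 0.611, and 0.0316 with no filter), with control 2 at 21.9 CPM and the other controls at 46.7 to 61.2 CPM. Nr4a2, a nuclear receptor of subplate cells, had 0.46 (SE 0.422, adjusted p = 0.849). Ccn2, Cplx3 and Moxd1 had 22, 4 and 33 counts over all 12 libraries and were too low to test. The list median was -0.03, and the list shift missed the threshold (camera adjusted p = 0.133, adjusted p = 0.341 with an estimated correlation). It passed without mutant 4 (0.0161), without the 2 shallowest libraries (0.0386), in females alone (0.0125), without the sex term (0.0197) and without both covariates (0.0158), always downward, and its range over all alternatives was 0.0125 to 0.442.

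Markers of the other cortical layers gave no call. Upper-layer and callosal markers had 15 measured members, 0 called by edgeR or adjusted over the list alone, and a camera adjusted p of 0.511. Bcl11b, a regulator of layer 5 subcerebral neurons, had 0.20 (SE 0.164, adjusted p = 0.819), and its list of 8 measured genes had a camera adjusted p of 0.776.

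**Figure D3:**
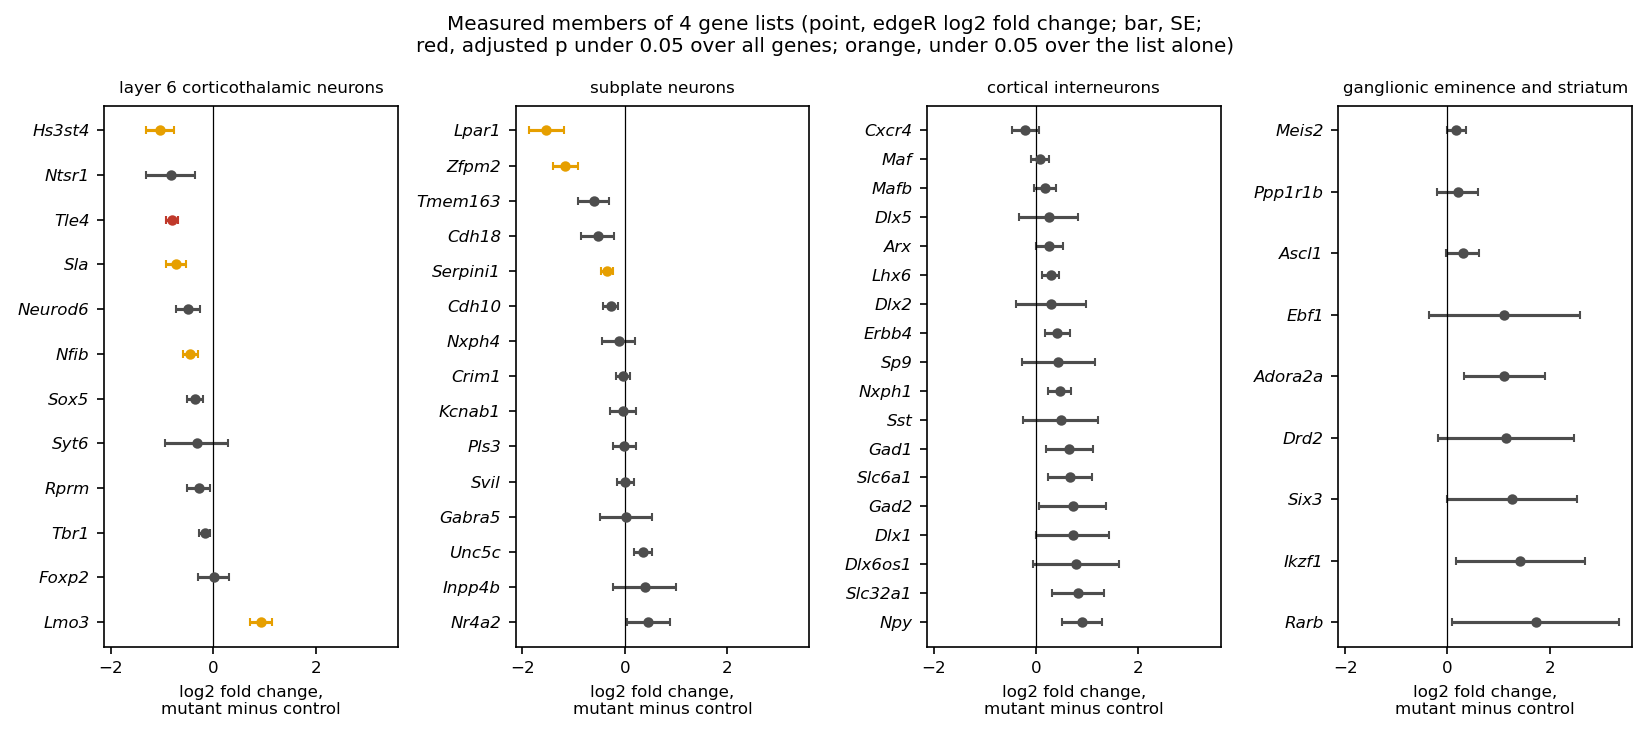
Log2 fold change of mutant minus control (horizontal axis, point) with its SE (bar) for each measured member of 4 gene lists (vertical axis), in red where the adjusted p over all genes is under 0.05 and in orange where it is so over the list alone. Tle4 is the 1 red point, 10 of 12 layer 6 markers and 10 of 15 subplate markers lie left of 0, and 17 of 18 interneuron and 9 of 9 ganglionic eminence markers lie right of it.

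Markers of cortical interneurons, which arise outside the Emx1 lineage, rose as a list with no single gene past the threshold over all genes (camera adjusted p = 0.00284, adjusted p = 0.676 with an estimated correlation): 17 of 18 measured members were positive, 0 were called and 0 passed adjusted over the list alone. Gad2, which makes the transmitter GABA, had a log2 fold change of 0.71 (SE 0.654), and Dlx1, a homeobox gene of the ventral forebrain, had 0.72 (SE 0.717). Without control 1 (0.0882) or without both covariates (0.0526) the interneuron list no longer passed, and it passed in 24 of 29 alternatives (1.87e-05 to 0.676). Ganglionic eminence and striatum markers moved with the interneuron list from library to library: all 9 measured members were positive, among them Ebf1 (1.11, SE 1.47) and Rarb (1.72, SE 1.62). As a list they did not pass with all libraries (camera adjusted p = 0.117, adjusted p = 0.959 with an estimated correlation). They passed in 11 of 29 alternatives, over a range of 1.75e-07 to 0.959, among them those without mutant 2 (0.0108), mutant 4 (2.02e-05), mutant 5 (0.0169), control 2 (0.0350), control 4 (0.0417) or control 6 (0.0460). The mean score of these striatal markers ran from -1.22 to 1.30 in mutants and from -1.46 to 1.41 in controls. With that score as a covariate, chosen after seeing the data, the interneuron list had a camera adjusted p of 0.0669, the layer 6 list 0.000346, and 27 genes were lower and 7 higher.

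**Figure D4:**
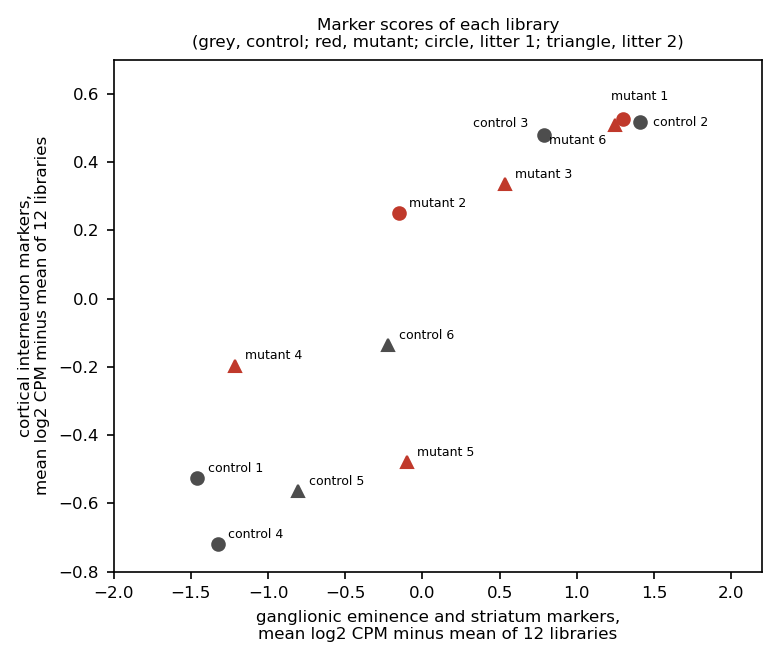
Mean score of cortical interneuron markers (vertical axis) against that of ganglionic eminence and striatum markers (horizontal axis), each in log2 CPM minus the mean of the 12 libraries, for control (grey) and mutant (red) libraries of litter 1 (circles) and litter 2 (triangles). Both genotypes span the plot, with Pearson r = 0.888 after the group means are removed.

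Oligodendrocyte precursor markers rose as a list of 4 measured genes (camera adjusted p = 0.00284, adjusted p = 0.241 with an estimated correlation). The list passed in 25 of 28 alternatives (0.000277 to 0.241), and not without both covariates (0.148). All 4 members did not pass over all genes, and adjusted over the list alone 1 was higher, Cspg4, the NG2 proteoglycan (0.98, SE 0.337), although its levels without the litter and sex terms were 8.27 ± 3.51 CPM in mutants and 7.74 ± 3.78 CPM in controls. Lhfpl3 had 1.26 (SE 0.490), with 257 ± 119 CPM in mutants and 119 ± 60.8 CPM in controls. Pericyte markers, also 4 measured genes and also holding Cspg4, rose as a list (camera adjusted p = 0.0342, adjusted p = 0.241 with an estimated correlation), with 0 called over all genes and 1 higher adjusted over the list alone. The pericyte list no longer passed without control 6 (0.226), mutant 1 (0.0673), mutant 4 (0.0516) or mutant 6 (0.0523). Nor did it pass without the litter term (0.257), the sex term (0.239) or both (0.820), and it passed in 12 of 28 alternatives (0.0168 to 0.820). Its score, which is free of these terms, was 0.048 ± 0.283 in mutants and -0.048 ± 0.284 in controls (SD, n = 6 each). Mitochondrial transcripts fell as a list (camera adjusted p = 0.00579, adjusted p = 0.648 with an estimated correlation): 9 of 9 measured members were negative, 0 were called and 0 passed adjusted over the list alone. The transcript mt-Nd5 had -0.59 (SE 0.253), while the plain share of mitochondrial counts was 1.19% ± 0.350 in mutants and 1.23% ± 0.444 in controls (SD, n = 6 each, two-sided exact permutation p = 0.877). The call of the mitochondrial list was lost without the sex term (camera adjusted p = 0.487) and without both covariates (0.820). Without control 6 the mitochondrial list did not pass (0.744), and its value was 0.930 in litter 1 alone (against control 1) and 7.25e-05 in litter 2 alone, with 22 of 28 alternatives passing (7.25e-05 to 0.930).

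The other 16 tested lists, none of which passed, had camera adjusted p values that ranged up to 0.985. No member of these lists passed over all genes, including those named below as lower or higher over the list alone. Radial glia markers had 22 measured genes and 0.150, red blood cell markers 3 genes and 0.133, and cell cycle genes 33 genes and 0.543. Radial glia passed without control 2 (0.0453) or mutant 2 (0.0147), red blood cell markers without control 6 (0.0460), and the cell cycle list without control 1 (0.0209). Intermediate progenitor markers had 0.776, with 14 measured genes of which, adjusted over the list alone, 3 were lower, Rhbdl3 (-1.24, SE 0.237), Sstr2 (-0.70, SE 0.256) and Mfng (-0.58, SE 0.209), and 1 was higher, Gadd45g (0.76, SE 0.251). BAF and PBAF subunits had 0.776, with 28 measured genes and 1 lower adjusted over the list alone, Dpf3 (-0.96, SE 0.203). Synapse genes had 0.901, with Stx1a (0.72, SE 0.186) and Syn2 (0.57, SE 0.163) higher and Nlgn1 (-0.69, SE 0.150) lower adjusted over the list alone. Cortical hem and hippocampus markers had 0.820, with Rspo3 (-0.92, SE 0.273) lower adjusted over the list alone, and passed without control 6 (0.00531). Axon guidance genes (62 measured) and p53 targets (12) had 0.776, hypoxia and glycolysis genes (17) 0.759, Wnt targets (7) and Cajal-Retzius markers (9) 0.820, and endothelial (11), thalamus (5) and integrated stress response genes (14) 0.962. Immediate early genes (7) had 0.985. Median, mean and test differed in sign for Cajal-Retzius markers (median -0.06, mean 0.07, test upward), synapse genes (median -0.06, mean 0.0025, test downward), endothelial markers (median 0.06, mean -0.04, test downward), thalamus markers (median -0.05, mean 0.15, test downward) and immediate early genes (median -0.07, mean -0.26, test upward). Hox and choroid plexus genes had 0 measured members, and meningeal and microglial markers had 1 each, so these 4 lists were not tested.

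None of the 5 list calls held with an estimated correlation, and fry called 1 list, layer 6. Fisher's exact test found 0 lists over-represented among the 17 lower or the 6 higher genes after adjustment; at an unadjusted p under 0.05 stood layer 6 (p = 0.0189, adjusted p = 0.985) and extracellular matrix (p = 0.0406, adjusted p = 1), each with 1 lower gene.

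Whether the mutant effect differed between the litters was asked with an interaction term. No gene passed with edgeR (776 at an unadjusted p under 0.05), limma-voom gave 0 and DESeq2 gave 6, and edgeR gave 1 without control 1 or control 5. Among the 23 genes the largest evidence for a difference was that of Lrrtm4 (interaction 0.63, SE 0.223, edgeR adjusted p = 0.552), which did not pass. Lists were put to this test only after the other results were seen. Radial glia and cell cycle lists moved lower in litter 2 than in litter 1 (camera adjusted p = 1.43e-05 for each), as did mitochondrial transcripts (0.0141), while those of Cajal-Retzius markers (0.00582) and synapse genes (0.0304) moved higher. With an estimated correlation 0 of 26 lists passed (lowest adjusted p = 0.633), and the litter 1 side rests largely on control 1. In simulated counts 146 of 191 genes with a 4-fold effect in litter 2 alone were called, so smaller differences between the litters could be missed at this depth and group size.

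Between the sexes 1 gene passed, Xist, which was lower in males, with 742 genes at an unadjusted p under 0.05. The filter, which groups by genotype, kept 1 of the 6 genes listed for the sex check, Xist. The Y-linked genes of that check were therefore not tested and are missing from the count. DESeq2 gave 2 genes and limma-voom 1. Xist and Y-linked genes matched the labelled sex in 12 of 12 libraries. Without control 1, 1 of 2 control females, the number of genes was 17, and it was 5 without control 6, mutant 1, mutant 2 or mutant 6 and 6 without mutant 3 or mutant 5.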

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

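The test of the gene-span trend, the test of the ganglionic eminence markers, the interaction test over gene lists and the splits within litter and sex were chosen only after results were seen, and so were the alternatives without the 2 shallowest libraries and with the striatal marker score.

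Single libraries lay far from the other 5 of their group in 6 of 120 groups of values, where chance gives about 6, so as a set they are no more than chance gives. Mutant 6 had 23.2 CPM of Efs, with the other mutants at 10.6 to 15.2 CPM. Control 2 had 21.9 CPM of Tmem163, with the other controls at 46.7 to 61.2 CPM. Mutant 4, the 1 male mutant and a shallow library, had a subplate score of 0.20 (other mutants -0.26 to -0.17), a cell cycle score of -0.49 (0.07 to 0.34) and an axon guidance score of 0.068 (-0.02 to 0.0028). Mutant 6 had a thalamus score of -0.38 (0.10 to 0.38).

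The mutant effect differed between the litters for 5 gene lists by the interaction term at camera's preset correlation: radial glia (adjusted p = 1.43e-05), cell cycle (1.43e-05), Cajal-Retzius cells (0.00582), mitochondrial transcripts (0.0141) and synapse (0.0304). None of them passed with an estimated correlation (lowest adjusted p = 0.633), and litter 1 holds 1 female control and no male mutant.

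Among 100 of the 462 splits of the 12 libraries into 6 and 6, 1 gave at least 23 genes, the real one. Those splits ignore how genotype overlaps litter and sex. In the 24 splits that keep this overlap, labels were exchanged only among libraries alike in litter and sex. The real one gave 23 genes and the other 23 splits gave 0. Its share is the smallest that 24 splits allow (0.0417), so chance is unlikely for the number of genes but not firmly excluded. The highest of the unrestricted splits but the real one gave 18, with 5 of the 6 libraries on 1 side being the 5 with the highest striatal scores, and 87 of the others gave 0. For the number of gene lists chance cannot be excluded: 29 of 100 splits gave at least the real 5, and the highest of the others gave 10. For the sexes the number leaves out the Y-linked genes of the sex check, which the filter had removed. Of 100 splits, 12 gave at least the real 1 gene, so the number alone does not exclude chance. That gene is Xist (log2 fold change -8.15, adjusted p = 9.28e-05), which with Y-linked genes matched the label in 12 of 12 libraries, and for it chance is excluded. The highest of those splits, with 292 genes, points to a structure of the samples, since 4 of the 5 libraries on its smaller side are among the 5 with the highest striatal scores.

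With the sex term 23 genes were called, and 77 without it. That differences between the sexes were counted as genotype is argued against by the size of the change. Over the 55 genes that lost their call, the log2 fold change with the sex term was a median of 0.948 of that without it (95% interval 0.919 to 0.984). All 55 had the same sign in females alone, which adds little, since the females include 5 of the mutants in which the genes were chosen. The standard errors of the 55 genes were 1.12 times as large (1.11 to 1.15), as a loss of precision from the overlap of sex and genotype would give. A larger standard error was largely given in advance by that overlap and by picking genes that lost their call. The ratio therefore does not test that account. Both intervals resample the 55 genes, which share the same 12 libraries, so they do not measure the spread over embryos. All 55 had an unadjusted p under 0.05 with the sex term, so the difference in number may come largely from precision. An effect of genotype that differs between the sexes stays open, as untested, since only 1 mutant was male.

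The genes lower in mutants were long, with a median span of 185.3 kb against 31.8 kb for all genes tested and 58.9 kb for the higher genes, and 12 of 17 spanned over 100 kb (19.7% of genes tested did). A trend on gene length in the libraries is argued against as the whole cause by its size: removing it moved the 17 log2 fold changes by a median of 0.02 and at most 0.03, against a smallest change of -0.62 (Cdk6, SE 0.107). So small a correction left 16 of the 17 calls in place, which adds little, and the call of Hs3st5 ended on a larger SE (0.175 to 0.201) at log2 fold changes of -1.09 and -1.08. More counts on long genes are argued against too: the median span lay at percentile 100 of 10000 sets matched on mean counts, whose median was 63.1 kb and the upper end of whose central 95% was 113.8 kb. Any other cause of the long spans, the genotype included, was not tested, and whether intron reads were counted is not given in the sources used here.

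Interneuron markers rose as a list in mutants at camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.676) and with fry (0.650). More or less ganglionic eminence tissue in single dissections may account for part of it: with group means removed, the interneuron score followed the score of ganglionic eminence and striatum markers, which share 0 genes with it, over the 12 libraries (Pearson r = 0.888, permutation p = 0.00023; Spearman rho = 0.818, permutation p = 0.0018). Pearson r was 0.874 without the 2 farthest libraries, 0.954 within litter 1 and 0.764 within litter 2, and among the most abundant striatal markers Ebf1 stood at 386 ± 321 CPM in mutants and 263 ± 282 CPM in controls. A lower share of Emx1-lineage cells, which would raise the markers of all other types alike, cannot be told apart: interneuron minus endothelial change was 0.46 (95% interval -0.34 to 1.26), an interval too wide to separate them. The endothelial change alone was -0.04 (-0.20 to 0.12), and the interneuron change alone was 0.42 (-0.39 to 1.24). Endothelial markers thus showed no rise as large as 0.42, but the wide interneuron interval overlaps theirs and leaves a smaller shared rise open. A change in interneurons themselves with genotype stays open as well, as untested.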

How the results depend on the processing

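The alternatives at equal depth, without the 2 shallowest libraries, with the span trend removed and with the striatal score were chosen after seeing the data. Litter 1 alone, with its sex term, sets 2 mutants against control 1 only. All 23 genes kept their sign wherever they were tested (18 of them at equal depth), with median ratios to the reported values from 0.933 to 1.15, and Arid1a stayed negative in 31 of 31 alternatives (-0.36 to -0.19) and never passed. The 23 genes were chosen in these same libraries, which each alternative refits in whole or in part. Their shared signs and ratios were thus largely given in advance. The counts of 6 higher and 17 lower genes moved more. Higher and lower genes were 2 and 19 without the litter term, 14 and 63 without the sex term, 23 and 118 without both, 18 and 77 with DESeq2, 3 and 16 with limma-voom, 62 and 199 with no filter, 7 and 30 with the filter at 1 CPM, 6 and 27 with robust = FALSE, 1 and 6 at an adjusted p under 0.01, 2 and 3 in litter 1, 23 and 41 in litter 2, 7 and 37 in females, 3 and 20 at equal depth (10 of them among the 23 reported), 0 and 0 without the 2 shallowest libraries, and 7 and 27 with the striatal score as covariate. Leaving out each library in turn gave 0 to 10 higher and 5 to 45 lower genes. Among the 23 reported were 11 of the 64 genes in litter 2, 13 of the 44 in females and 3 of the 9 without control 6. The stricter threshold lowers the count by construction. Single litters and left-out libraries hold fewer samples, yet the count rose in litter 2 alone and without some single controls. For these and the other alternatives the cause was not tested. All 95 DESeq2 genes had the same sign in edgeR. With no filter 246 of 261 genes were among those tested in the reported fit.

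Against 5 gene lists as reported, equal depth and the striatal covariate gave 3 each, an estimated correlation 0, fry 1 and litter 2 alone 10, and leaving out each library 4 to 7. For the interaction, against 0 genes by edgeR (776 at an unadjusted p under 0.05), DESeq2 gave 6, females alone 22 and no filter 75, and leaving out each library 0 to 1. Over-represented lists, 0 as reported, were 1 in females, in litter 2, without covariates, with no filter and with robust = FALSE. Against 1 gene between the sexes, DESeq2 and equal depth gave 2, leaving out X, Y and mitochondrial genes 0 (704 at an unadjusted p under 0.05; it removes Xist), litter 1 alone 6, litter 2 alone 7, no filter 76, the filter at 1 CPM 4, the libraries without the 2 shallowest 5, and leaving out each library 1 to 17. The cause was not tested.

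List directions that turned were those of Cajal-Retzius markers (0.820 as reported), downward in litter 1 (adjusted p = 0.00120, 1 informative control), the cell cycle list (0.543 as reported), upward in females (0.0347), in litter 1 (0.00120), without covariates (0.000632) and without the sex term (0.0472), and mitochondrial transcripts, the 1 of them called as reported, upward in litter 1 without passing (0.930). The cause was not tested, and those of litter 1 rest on control 1. Of the other alternatives' values for lists, 678 kept direction and side of the threshold or had no call in either, 31 newly passed and 32 no longer did. For 30 single genes, the called ones and those fixed beforehand, 700 did, 7 newly passed and 218 no longer did. Values that never passed changed sign in 92 list and 10 gene cases, which are counted with those that kept their side. At these depths and group sizes 1.5-fold changes were called in 34.5% of simulated genes, and how far depth rather than group size limits such calls was not tested.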

Other observations

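The comparison of gene lists between litters, the litter splits within genotype and sex, and the tests of litter age and of the sulfation enzymes were chosen only after the patterns they concern were seen, and before their own results were.

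The litters differed in more genes than the genotypes did. Litter 2 against litter 1 gave 74 higher and 66 lower genes, 4 of them also called for genotype, with 1641 at an unadjusted p under 0.05. Tnc, the matrix protein tenascin C, was lower in litter 2 (log2 fold change -1.95, adjusted p = 2.15e-05), as was Sema3c, a guidance cue (-0.90, adjusted p = 0.00406). Tbr1 (0.74, adjusted p = 0.00125) and Hmgb2, a chromatin protein of dividing cells (1.00, adjusted p = 0.00406), were higher. These 4 genes were chosen after their values were seen. As lists, cell cycle genes (camera adjusted p = 2.18e-07), intermediate progenitor markers (0.00731) and BAF and PBAF subunits (0.0174) were higher in litter 2, and red blood cell (0.000725) and interneuron markers (0.0141) were lower. None passed with an estimated correlation (lowest adjusted p = 0.425). Among 100 splits of the libraries, 1 gave at least the real 140 genes, and the highest of the others gave 107, with the 5 highest striatal scores on 1 side. Of the 80 splits that exchange litter labels only among libraries alike in genotype and sex, 1 did, the real one, and the highest of the others gave 21. Chance is thus unlikely for the number of genes, at the smallest share that 80 splits allow (0.0125).

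A difference in developmental age between the litters is a candidate explanation that these values leave open, and it predicts that progenitor or cell cycle lists and the synapse list pass in opposite directions. Cell cycle and intermediate progenitor lists passed upward, calls lost with an estimated correlation (adjusted p = 0.515 for both), and radial glia, the other progenitor list, had members that moved both ways (fry mixed adjusted p = 6.76e-08) and no net shift called (camera adjusted p = 0.997), which decides nothing. The synapse list moved downward but missed the threshold (adjusted p = 0.0768, unadjusted p = 0.0236). A missed threshold does not show that the list stayed level, so the bound written beforehand, which asked only for a missed threshold, was too weak to exclude an age difference. The labels give the same embryonic day for both litters.

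Sulf1, Hs3st5 and Ust, lower in mutants, all change the sulfation of glycosaminoglycans, and a hypothesis was that such enzymes may be lower as a class. Over 19 measured of 25 listed other enzymes, the mean log2 level of mutants minus controls was -0.12 (95% interval -0.31 to 0.08). That interval lies above the bound of -0.5 set for a fall of the class, which argues against a mean fall that large over the 19. A smaller fall, or a fall in part of the class, was not tested by this mean. Hs3st4, a heparan sulfate sulfotransferase of the layer 6 list (-1.04, SE 0.266), was measured but was not among the 19. Of the 19, 0 were called by edgeR, 4 had an unadjusted p under 0.05, 13 were negative and 6 positive, with Hs3st3b1 at -1.30 (SE 0.331, adjusted p = 0.130) and Hs6st3 at 0.86 (SE 0.269, adjusted p = 0.331).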
